A study of Mus musculus with 14 samples.

How the data were processed

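Total RNA of 14 mouse samples was labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols. The spot intensity used was the processed signal, which Agilent Feature Extraction had background-subtracted and detrended within each array without scaling between arrays, per the file headers. Mean and local background intensities, per the file headers, served an alternative. The headers name Feature Extraction 10.7.3.1, whereas the submitters' processing notes name 9.1, and the values do not settle which applies. The deposited value table holds log2 values of 41265 probes. Its sorted columns differed by at most 0.00141, so it was quantile normalized, and its columns correlated with the log2 processed intensity at 0.998 to 1.00 and had medians of 5.93. How its background was treated is not given in the sources used here.

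Each array had 45018 spots, of which 1639 controls were left out, as were 79 to 195 spots per array that the scanner software marked as outliers. Spots of a probe were averaged, giving 41174 probes. A probe took its gene name through its accession (27668 probes), its symbol (5589) or an older symbol (471) from a RefSeq table for GRCm38.p6, used for names only, and 7446 probes kept the file's name. Of 27343 gene names 9043 had several probes, and the probe with the highest mean over the 12 replicated arrays stood for the gene. Coordinates are those of the files, in mm9. The log2 processed intensity minus the array's 75th percentile was analysed. Genes were kept whose probe was well above background on all arrays of at least 1 of the 4 replicated groups and had values on at least 2 arrays of each, which left 17723.

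Groups came from the labels. The 12 progenitor and myeloid cell arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3, data.table version 1.17.8, statmod 1.5.0), so that all groups shared 1 estimate of the spread (8 residual and 1.95 prior degrees of freedom, median residual SD 0.183). Contrasts were Rheb1-/- minus wild type in each cell type, the difference of these, and myeloid cells minus progenitors in each genotype. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, two-sided. The labels speak of independent experiments but tie no sample to an animal, so p-values measure the spread among these samples. Correlation-adjusted tests (camera, preset correlation 0.01) were run on 29 gene lists, adjusted over the lists, and camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, stand beside them. List members were also adjusted over the list alone. Overlap was tested with Fisher's exact test. The stem cell arrays, 1 per genotype, were described without a test, over genes well above background on both, with 10000 random lists from 20 expression bins.

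Where a gene was not well above background on any array of the lower group, the text gives "at least N-fold", the higher group's mean against the mean, per array, of the higher of the lowest well-measured signal and the gene's own. Where it was so on some arrays, their number is given. These bounds can fail with normexp. The named genes are Rheb, then the 8 largest rises and 8 largest falls (5 and 5 for the difference and the cell types) among passing genes with an official symbol whose groups did not overlap and which were well above background on all arrays of the higher group. Where fewer passed, those of smallest p filled up as values only. Each list gave up to 3 passing members of smallest p or, where none passed, the member of smallest p as a value. In stem cells the 8 largest differences each way were named. Groups, lists, tests, the naming rule and the settings below were fixed before the data were examined.

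The fit was tested on simulated data with 17693 genes, where the cell cycle list, shifted by 0.5, was called in both cell types and 0 of 28 other lists were. Of 100 genes changed by 1 on the log2 scale, 74% were recovered in progenitors and 75% in myeloid cells, and of 100 changed by 2, 93% and 86%, with 5 and 16 false calls among 17493 unchanged genes. Other settings tried were normexp correction with an offset of 50, quantile normalization, the deposited value table, the mean of a gene's probes, no filter and a filter requiring all 12 arrays, replicate number or slide as a block (slide fixed over all 14 arrays or random), only the 4 progenitor arrays of slide 3, only the 6 arrays of a cell type, array weights, an intensity trend with a robust prior, a 2-fold minimum, and each of the 12 arrays left out. Chosen after seeing the data were autosomal genes alone and 10 arrays without wild-type progenitor array 1 and Rheb1-/- progenitor array 3. No genome sequence was used here. Some genes that the naming rule takes are not reported here.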

Results

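Gene expression was measured in 14 samples of mouse blood-forming cells, each on 1 single-colour Agilent array. The samples came from wild-type mice and from mice whose floxed Rheb1 alleles were recombined by Vav1-cre, which is active in blood cells. Rheb1 (official symbol Rheb) encodes the small GTPase that switches on mTORC1, the kinase complex that couples nutrients and growth factors to protein synthesis. Myeloid progenitors and myeloid cells were each measured in 3 wild-type and 3 Rheb1-/- samples, and hematopoietic stem cells in 1 sample of each genotype. The series addresses the part of Rheb1 and mTORC1 in macrophage differentiation and phagocytosis. Between 58.5% and 67.6% of the spots on an array were well above background, none was saturated, and replicates correlated across genes at 0.988 to 0.992. Few arrays limit the precision.

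The arrays lay on 4 slides. Slide 1 held the 3 wild-type myeloid cell arrays and the Rheb1-/- stem cell array, and slide 2 the wild-type stem cell array and wild-type progenitor array 1. Slide 3 held wild-type progenitor arrays 2 and 3 with Rheb1-/- progenitor arrays 1 and 2, and slide 4 held Rheb1-/- progenitor array 3 and the 3 Rheb1-/- myeloid cell arrays. Slide 2 was scanned on another day than the rest. Genotype and slide could therefore not be told apart in myeloid cells or stem cells, whereas both genotypes of the progenitors shared slide 3, and their difference on that slide is given as the within-slide value. It equals the value with slide as a block over all 14 arrays. The first principal component of the 12 replicated arrays held 79.0% of the variance and separated the cell types. The second separated wild-type from Rheb1-/- myeloid cells.

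**Figure D1:**
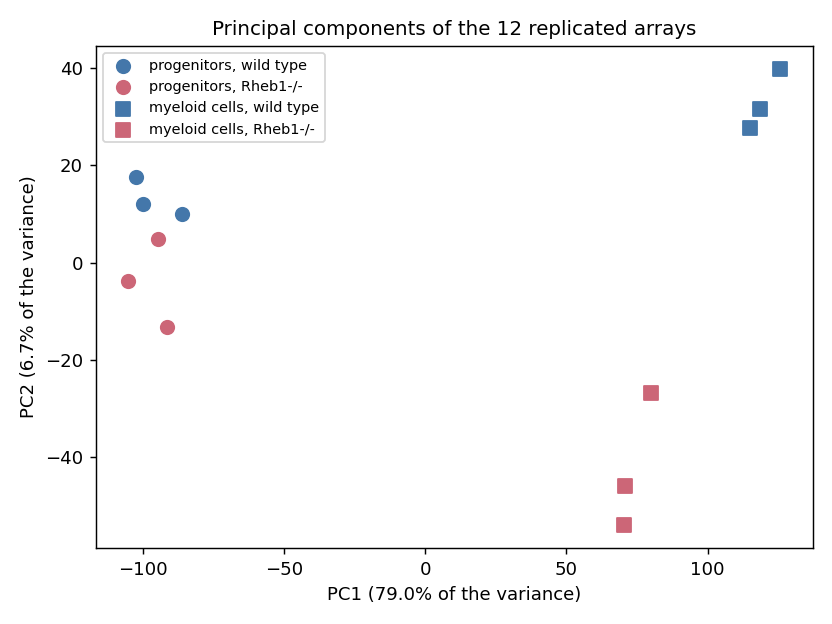
Principal components of the 12 replicated arrays, with PC1 (79.0% of the variance) on the x axis and PC2 on the y axis, in arbitrary units, 1 point per array and colours for genotype. Wild-type myeloid cells lie at 115 to 126 on PC1 and Rheb1-/- myeloid cells at 70.4 to 80.1, while the progenitors of both genotypes lie at -105 to -86.2.

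Rheb itself was examined first, as a check of the genotype labels. Its signal was lower on each Rheb1-/- array than on every wild-type array of the same cell type. In myeloid cells Rheb fell 1.85-fold (log2 -0.89 ± 0.22 SE, n = 3 per genotype, limma adjusted p = 0.0117). In progenitors the log2 difference was -1.08 ± 0.22 SE, a 2.12-fold lower level that did not pass (limma adjusted p = 0.0940), and it was -0.96 within the slide. Without Rheb1-/- progenitor array 1 the progenitor difference was -1.30 and passed (limma adjusted p = 0.0397; range over 24 alternatives 0.0397 to 0.554). Wild-type progenitor arrays read 3.94, 4.04 and 3.78 (mean 3.92 ± 0.13 SD, n = 3) and Rheb1-/- progenitor arrays 3.26, 2.65 and 2.60 (2.84 ± 0.37 SD, n = 3), in log2 units above the array's 75th percentile. Wild-type myeloid cells averaged 3.09 ± 0.40 and Rheb1-/- myeloid cells 2.20 ± 0.14 (SD, n = 3 each). The wild-type stem cell array read 3.46 and the Rheb1-/- one 2.26. The array holds 1 probe for Rheb, which the file coordinates place on the minus strand of mm9 chromosome 5, at 24308641 to 24308675. Whether it lies in the deleted part of the gene is not given in the sources used here.

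**Figure D2:**
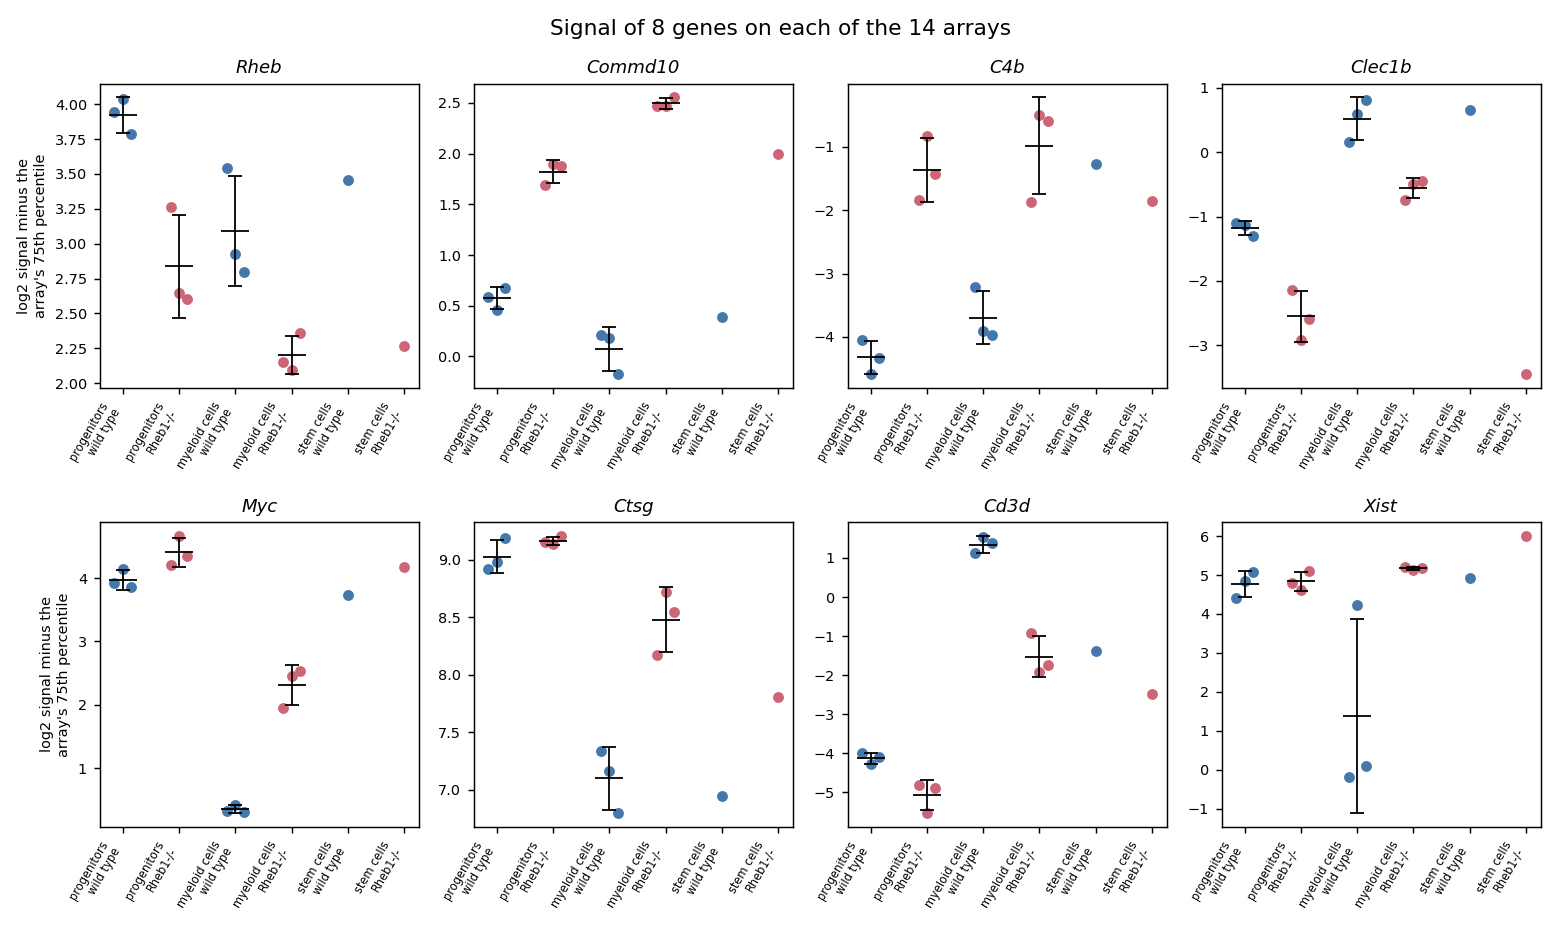
Log2 signal minus the array's 75th percentile (y axis, a separate scale per gene) for 8 genes in the 6 groups (x axis), 1 point per array, with the mean and SD where a group has 3 arrays. Rheb averaged 3.09 in wild-type and 2.20 in Rheb1-/- myeloid cells, and Commd10 rose by 1.25 in progenitors and 2.42 in myeloid cells.

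In myeloid progenitors few single genes passed the test, but the genes of megakaryocytes and platelets, of sterol synthesis and of the interferon response were lower as groups in Rheb1-/- cells by camera with its preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.131, 0.131 and 0.453). The complement component C4b rose 7.74-fold (log2 2.95 ± 0.38 SE, n = 3 per genotype, limma adjusted p = 0.0345; within the slide 3.12). Commd10, a member of the COMMD family, rose 2.38-fold (1.25 ± 0.12, limma adjusted p = 0.00511; within the slide 1.22). Dgat2, which makes triacylglycerol, rose 2.08-fold (1.06 ± 0.13, limma adjusted p = 0.0345; within the slide 0.97). The alanine aminotransferase Gpt2 fell 1.64-fold (-0.71 ± 0.07, limma adjusted p = 0.00646; within the slide -0.73). The interferon-inducible gene Ifi207 fell 2.67-fold (-1.42, within the slide -1.41).

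In all, 13 of 17723 genes passed limma's adjusted p of 0.05, 9 higher and 4 lower (7 and 20 with normexp), and 2138 had an unadjusted p under 0.05. The genotypes did not overlap in 3545 genes (20%, 10% by chance). Sva rose at least 1.77-fold (fitted log2 2.84, within the slide 2.63) and the immunoglobulin segment Igkv4-86 at least 1.23-fold (1.72, within the slide 1.56). The kinesin gene Kif1a, above background on 1 of 3 wild-type arrays, rose by 1.63 (within the slide 1.81), and Ms4a7, a gene of macrophages above background on 1 of 3 Rheb1-/- arrays, fell by 1.83 (within the slide -1.64). Called genes outside the naming rule, named after their values were seen, were 4932439E07Rik, Olfr1358 and Mfsd13b, which rose by 1.61, 1.35 and 1.22, and a probe without a gene name that fell. Of the genes next in order, which did not pass, the endothelial receptor Kdr differed by -1.41, the platelet receptor Clec1b by -1.37, Zfp105 by -0.66, Mxra7 by -0.53, Tsga10ip by 1.41 (above background on 2 of 3 wild-type arrays) and Ifitm5 by at least 1.67-fold. With slide as a block Sva and Kif1a passed (limma adjusted p 0.0242 each) and other named genes did not (0.0906 to 0.221). The count was 6 without wild-type array 1, 53 and 54 without wild-type arrays 2 and 3, 81, 8 and 6 without Rheb1-/- arrays 1, 2 and 3, and 6 without wild-type myeloid cell array 1 or 2. Sva, Kif1a, Commd10 and Gpt2 passed whichever of the 12 arrays was left out, while C4b (adjusted p up to 0.124), Dgat2 (0.124) and Ms4a7 (0.124) reached their highest value without Rheb1-/- array 3, and Ifi207 (0.139) and Igkv4-86 (0.144) without Rheb1-/- array 2. Normexp did not call Sva (0.40, adjusted p = 0.681), Kif1a (0.35, 0.681), Gpt2 (-0.58, 0.0557), Ifi207, Igkv4-86 or Ms4a7. Over all alternatives the call was kept in 23 of 27 for Sva, 20 of 27 for Kif1a, 23 of 28 for Commd10, 21 of 28 for Gpt2, 13 of 28 for C4b, 14 of 28 for Dgat2, 12 of 28 for Ifi207, 12 of 27 for Igkv4-86 and 9 of 27 for Ms4a7.

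Among the gene lists fixed in advance, the markers of megakaryocytes and platelets fell furthest. Their median log2 difference was -1.45, and -1.19 within the slide. No member passed limma's adjusted p over all genes (8 did with normexp, Pf4 and Vwf among them), 16 of 18 had an unadjusted p under 0.05, and 16 fell adjusted over the list alone, among them Clec1b (-1.37), the clotting factor Vwf (-1.63) and the chemokine Pf4 of platelet granules (-2.19). The list passed as a whole (camera adjusted p = 3.08e-19, adjusted p = 0.131 with estimated correlation, 1.01e-31 to 0.131 over 26 alternatives; 1.95e-13 with slide as a block). Sterol and fatty acid synthesis also fell (median -0.36, within the slide -0.35, camera adjusted p = 8.69e-14, adjusted p = 0.131 with estimated correlation, 1.79e-16 to 0.131 over 26 alternatives). Of its 27 genes 12 fell adjusted over the list alone, 16 were lower at an unadjusted p under 0.05, and limma called none over all genes. Interferon response genes fell as a list (median -0.34, within the slide -0.63, camera adjusted p = 8.81e-09, adjusted p = 0.453 with estimated correlation, 1.58e-16 to 0.453 over 26 alternatives), with 5 of 33 falling adjusted over the list alone and the antiviral GTPase Mx1 at -0.64. The markers of stroma and endothelium were lower (median -0.46, within the slide -0.95, camera adjusted p = 2.06e-04, adjusted p = 0.329 with estimated correlation, 2.70e-06 to 0.329 over 26 alternatives), 4 of 13 falling adjusted over the list alone, with Kdr and Vwf among the members.

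Markers of other blood lineages moved with these groups. Erythroid markers fell as a list (median -0.65, within the slide -0.60, camera adjusted p = 9.50e-06, adjusted p = 0.504 with estimated correlation, 1.49e-07 to 0.504 over 26 alternatives), the red cell regulator Gata1 differing by -0.91. Eosinophil, basophil and mast cell markers also fell (median -0.61, within the slide -0.36, camera adjusted p = 9.81e-06, adjusted p = 0.453 with estimated correlation, 2.11e-09 to 0.453 over 26 alternatives), 1 of 20 adjusted over the list alone, with the histamine-making enzyme Hdc at -0.62. Stem cell markers fell (median -0.34, within the slide -0.25, camera adjusted p = 0.00114, adjusted p = 0.453 with estimated correlation, 1.32e-05 to 0.453 over 26 alternatives), 2 of 29 adjusted over the list alone. Monocyte and macrophage differentiation genes fell (median -0.17, within the slide -0.24, camera adjusted p = 2.05e-04, adjusted p = 0.453 with estimated correlation, 8.11e-07 to 0.453 over 26 alternatives), 1 of 43 passing over all genes (Ms4a7) and 4 adjusted over the list alone. T and NK cell markers had a median of 0.29 (within the slide 0.26) and did not pass (camera adjusted p = 0.128, adjusted p = 0.773 with estimated correlation, 0.0214 to 0.773 over 26 alternatives), with Zap70 at 0.52. The list passed without wild-type array 1 (adjusted p = 0.0316) or Rheb1-/- array 2 (0.0223). B cell markers (median 0.05, which turned to -0.02 with the mean of a gene's probes; adjusted p = 0.719; Ebf1 0.63) and dendritic cell markers (median -0.03, within the slide 0.41; adjusted p = 0.734; Irf8 -0.31) did not pass. With slide as a block the stem cell markers no longer passed (0.0871).

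The ribosomal protein genes and their partners rose as a list by a small amount (median 0.18, within the slide 0.11, 0.08 with quantile normalization or the deposited values, camera adjusted p = 2.72e-12, adjusted p = 0.465 with estimated correlation, 3.88e-21 to 0.465 over 26 alternatives), all 80 lying above 0, with 1 rising adjusted over the list alone and Tpt1, a growth-linked protein, at 0.46. Ribosome biogenesis also rose (median 0.10, within the slide 0.10, camera adjusted p = 0.0310, adjusted p = 0.593 with estimated correlation, 0.00296 to 0.593 over 26 alternatives), with Myc at 0.43. It did not pass without wild-type array 3 (adjusted p = 0.519) or Rheb1-/- arrays 2 and 3 (0.260 and 0.0548). Immediate early and heat shock genes fell as a list (median -0.25, within the slide -0.19, camera adjusted p = 0.00223, adjusted p = 0.547 with estimated correlation, 1.46e-07 to 0.547 over 26 alternatives; Atf3 -0.80). MHC class II presentation also fell (-0.29, within the slide -0.14, camera adjusted p = 0.00254, adjusted p = 0.465 with estimated correlation, 4.15e-04 to 0.582 over 26 alternatives; Cd86 -0.75, above background on 2 of 3 wild-type arrays). ATF4 targets and amino acid supply fell too (-0.15, within the slide -0.12, camera adjusted p = 0.00922, adjusted p = 0.329 with estimated correlation, 0.00338 to 0.329 over 26 alternatives; the folate enzyme Mthfd2 -0.44). So did lysosome and phagosome genes (-0.04, within the slide -0.03, camera adjusted p = 0.0209, adjusted p = 0.504 with estimated correlation, 0.00470 to 0.504 over 26 alternatives; Cd63 -0.43). The cell cycle list fell (-0.07, within the slide -0.08, camera adjusted p = 0.0492, adjusted p = 0.773 with estimated correlation, 0.0254 to 0.773 over 26 alternatives; the replication licensing factor Cdt1 0.33). With slide as a block these 5 falling lists no longer passed (adjusted p 0.0736 to 0.404). Leaving out wild-type array 1 ended the call of MHC class II (adjusted p = 0.0834). Leaving out wild-type array 3 or Rheb1-/- array 2 or 3 ended that of lysosome genes (0.110, 0.0581 and 0.0699). Without wild-type array 1 or 3, Rheb1-/- array 1 or 3, wild-type myeloid cell array 2 or Rheb1-/- myeloid cell array 3 the cell cycle list no longer passed (0.0533 to 0.145).

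The remaining lists did not pass in progenitors. mTORC1 components had a median of -0.01 (within the slide 0.00, camera adjusted p = 0.152), and adjusted over the list alone 1 of 39 fell, Rheb itself. Phagocytic receptors and opsonins had a median of -0.06 (within the slide -0.06; adjusted p = 0.417), 4 of 39 rising and 4 falling adjusted over the list alone, with the scavenger receptor Lrp1 at 0.56. Medians were -0.02 for phagocytic signalling and actin (-0.03 within the slide; Dock1 0.32), -0.13 for NADPH oxidase and microbicidal enzymes (-0.18), -0.06 for autophagy (-0.06; Atg14 0.20) and -0.02 for mitochondrial respiration (-0.06; Nrf1 -0.25). Glycolysis and HIF1 targets had a median of 0.01 and a mean of -0.02 (-0.04 within the slide; Aldoc -0.72), and the median was below 0 under normexp, quantile normalization and the deposited values. Inflammatory cytokines and NF-kB targets had a median of -0.09 (-0.18 within the slide; Ccl3 -0.70), neutrophil primary granule genes 0.09 (0.00; Calr -0.25), neutrophil maturation genes 0.07 (-0.03; Cd33 0.90) and myeloid progenitor genes 0.10 (0.04; Cd63 -0.43). Of these, without 1 array, NADPH oxidase passed (wild-type array 2, adjusted p = 0.0377), as did neutrophil maturation (wild-type array 3, 4.49e-07) and inflammatory genes (wild-type array 2, 0.0339; Rheb1-/- array 1, 0.00312, or 3, 0.0346; Rheb1-/- myeloid cell array 1, 0.0405, or 2, 0.0493). Over all genes limma called no member of any list but Ms4a7, while at an unadjusted p under 0.05 a list had up to 11 higher and up to 16 lower members. Adjusted over the list alone, 1 MHC class II gene and 1 glycolysis gene fell, 1 maturation gene rose, 1 ATF4 target rose and 1 fell, and no member passed in the lists given without such a count. In all, 15 of the 29 lists passed camera with its preset correlation, 2 higher and 13 lower, and 9 with slide as a block. With the estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, while fry called 2.

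Myeloid cells differed far more by genotype. In Rheb1-/- myeloid cells the genes for ribosomal proteins, ribosome biogenesis, the cell cycle, neutrophil primary granules and the myeloid progenitor state were higher, and the markers of red cells, lymphocytes, dendritic cells, eosinophils and platelets, the interferon response and sterol synthesis were lower. With an estimated correlation none of these lists passed (camera adjusted p = 0.275 or higher). Of 17723 genes 6069 passed limma's adjusted p of 0.05 (34.2%), 2927 higher and 3142 lower, 421 and 974 of them by at least 2-fold. The genotypes did not overlap in 50.1% of genes (10% by chance). The median difference over all genes was -0.08. The arrays of each genotype lay together on a slide of their own, so slide and genotype could not be told apart.

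The basic leucine zipper genes Maff (9.73-fold; log2 3.28 ± 0.37 SE, n = 3 per genotype, limma adjusted p = 3.77e-04) and Fosl1 (8.47-fold) rose, with the chaperone clusterin (Clu, 8.45-fold), C4b (6.55-fold; 2.71 ± 0.38), Sva (at least 1.93-fold), and the cytoskeletal Tln2 (7.59-fold) and Tctex1d1 (6.17-fold), both above background on 2 of 3 wild-type arrays. Another probe of Tln2, above background on 5 arrays, gave -1.12. The largest falls included Klk1b24 (at least 28.0-fold), Fam71b (at least 9.09-fold), the collagen gene Col6a3 (at least 5.09-fold), Rec114 (14.7-fold; its other probe, above background on 1 array, gave 0.55, and the mean of both -1.67) and Olfr1255 (-4.29, above background on 1 of 3 Rheb1-/- arrays). Normexp gave smaller log2 differences, 2.04 for Maff, 1.74 for Fosl1, 1.79 for C4b, 1.05 for Tln2, 0.61 for Tctex1d1, -2.97 for Klk1b24, -1.57 for Fam71b, -1.41 for Col6a3 and -1.71 for Olfr1255, and did not call Sva (0.07, adjusted p = 0.790). Sex-linked genes also stood among the extremes. Xist, the RNA of the silenced X chromosome of females, rose 13.8-fold (3.79 ± 0.92 SE), reading -0.20, 4.24 and 0.09 on the wild-type arrays and 5.20, 5.14 and 5.17 on the Rheb1-/- arrays, and it did not pass with array weights (1.51, adjusted p = 0.234). The Y-linked genes Eif2s3y, Ddx3y and Kdm5d fell at least 81.6-fold, 32.9-fold and 8.36-fold, and none of the 3 was well above background on a Rheb1-/- myeloid cell array. Among autosomal genes alone, an alternative chosen after seeing the data, 5722 passed.

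Genes of protein synthesis rose together. Among ribosomal protein genes, of 80 measured genes 76 rose, 0 fell and 4 did not pass (78 rose and 0 fell adjusted over the list alone), with a median of 0.72 (camera adjusted p = 8.40e-32, adjusted p = 0.275 with estimated correlation, 7.72e-43 to 0.275 over 23 alternatives). Rps7 rose by 1.03. For ribosome biogenesis, of 30 measured genes 25 rose, 1 fell and 4 did not pass (26 rose and 1 fell adjusted over the list alone), with a median of 0.67 (camera adjusted p = 4.41e-13, adjusted p = 0.275 with estimated correlation, 4.08e-17 to 0.275 over 23 alternatives). Myc, the transcription factor that drives this programme, rose 3.87-fold (1.95 ± 0.17 SE, limma adjusted p = 1.81e-04), the snoRNP protein Nop58 by 1.22 and nucleophosmin (Npm1) by 1.19. In the cell cycle list, of 38 measured genes 27 rose, 1 fell and 10 did not pass (34 rose and 1 fell adjusted over the list alone), with a median of 0.61 (camera adjusted p = 5.25e-13, adjusted p = 0.275 with estimated correlation, 5.33e-17 to 0.275 over 23 alternatives). The replication genes Cdt1, Mcm6 and Mcm3 rose by 0.97, 0.89 and 0.68. Immediate early and heat shock genes rose as a list (median 0.47, camera adjusted p = 8.52e-04, adjusted p = 0.437 with estimated correlation, 2.22e-05 to 0.437 over 23 alternatives), 6 of 27 passing, among them Atf3 (1.96), Jun (1.53) and Hsp90aa1 (0.87), and 21 not passing (6 rising and 0 falling adjusted over the list alone).

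Genes of early myeloid stages rose as well. Of 9 primary granule genes 8 rose and 1 fell, both over all genes and adjusted over the list alone (median 1.19, camera adjusted p = 4.44e-05, adjusted p = 0.403 with estimated correlation, 5.64e-07 to 0.403 over 23 alternatives). The granule protease inhibitor cystatin F (Cst7) rose 2.83-fold, cathepsin G (Ctsg) 2.60-fold and Nkg7 2.40-fold. Of 20 myeloid progenitor genes 12 rose and 8 did not pass (12 and 0 rose and fell adjusted over the list alone, median 0.60, camera adjusted p = 9.17e-05, adjusted p = 0.275 with estimated correlation, 2.62e-06 to 0.275 over 23 alternatives), including the cell cycle kinase Cdk6 (1.11) and the stem cell factor receptor Kit (0.89). Neutrophil maturation genes fell as a list (median -0.35, camera adjusted p = 0.0310, adjusted p = 0.667 with estimated correlation, 0.00119 to 0.667 over 23 alternatives), with 2 rising, the zinc finger repressor Gfi1 (0.73) and Trem1 (0.98), 8 falling, such as the gelatinase Mmp9 (-0.96), and 22 not passing (2 and 8 adjusted over the list alone). That call ended without wild-type array 3 (adjusted p = 0.0673) or Rheb1-/- array 1 (0.0888). Stem cell markers did not pass as a list (median -0.42, camera adjusted p = 0.350, adjusted p = 0.697 with estimated correlation, 0.173 to 0.697 over 23 alternatives), 3 of 29 rising and 6 falling over all genes, 3 and 5 over the list alone. The homeobox gene Hoxa9 rose by 1.83 and Ly6a fell by 0.95.

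Of 5 lists of phagocyte genes 3 passed as lists. Among phagocytic receptors and opsonins, of 39 measured genes 4 rose, 13 fell and 22 did not pass (4 rose and 16 fell adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.0287, adjusted p = 0.403 with estimated correlation, 0.00606 to 0.403 over 23 alternatives). The receptor tyrosine kinase Axl and its ligand Gas6, which bind dying cells, fell 3.35-fold and 3.39-fold, and Cd93 rose by 0.80. In phagocytic signalling and actin machinery, of 41 measured genes 2 rose, 12 fell and 27 did not pass (2 rose and 12 fell adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.00956, adjusted p = 0.403 with estimated correlation, 1.14e-04 to 0.403 over 23 alternatives). Vav2 fell 4.49-fold, the myosin Myo1f by 0.72 and Arpc5 of the actin-nucleating Arp2/3 complex by 0.64. In monocyte and macrophage differentiation, of 43 measured genes 4 rose, 14 fell and 25 did not pass (4 rose and 16 fell adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0390, adjusted p = 0.492 with estimated correlation, 0.00210 to 0.492 over 23 alternatives). The haemoglobin scavenger receptor Cd163 fell 5.65-fold, Maf fell by 0.63 and Vcam1 rose by 0.94. The list did not pass without wild-type array 1 (adjusted p = 0.0646) or 2 (0.0604) or Rheb1-/- array 2 (0.108), nor did phagocytic receptors without wild-type array 2 (0.0503). Lysosome and phagosome genes (3 rose, 9 fell, 28 did not pass; 3 and 9 adjusted over the list alone) had a median of -0.21 and did not pass as a list (adjusted p = 0.281). The protease cathepsin L (Ctsl) rose 2.63-fold, the glycosidase Gla rose by 0.75 and the cholesterol exporter Npc1 fell by 0.59. NADPH oxidase and microbicidal enzymes (2 rose, 3 fell, 8 did not pass; 2 and 3 over the list alone) had a median of -0.10 (adjusted p = 0.407). The oxidase subunits Cyba and Ncf1 fell by 0.62 and 0.57, and the phagosomal metal transporter Slc11a1 by 1.08.

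Interferon response genes fell as a list (median -0.62, camera adjusted p = 1.44e-05, adjusted p = 0.403 with estimated correlation, 1.92e-07 to 0.403 over 23 alternatives), 17 of 33 falling, 16 not passing and 21 falling adjusted over the list alone. The antiviral genes Rsad2, Oasl2 and Rtp4 fell 4.61-fold, 3.51-fold and 2.56-fold. MHC class II genes fell (median -0.68, camera adjusted p = 0.0228, adjusted p = 0.446 with estimated correlation, 0.00157 to 0.446 over 23 alternatives), 4 of 13 passing and 4 adjusted over the list alone, with H2-Ob at least 3.02-fold lower, H2-DMb2 at -0.96 and H2-Oa at -0.68. That call ended without Rheb1-/- array 2 (adjusted p = 0.101). Inflammatory cytokines and NF-kB targets did not pass as a list (median -0.04, adjusted p = 0.745), with 3 rising, 7 falling and 14 not passing (3 and 7 adjusted over the list alone). The interleukin-1 receptor antagonist Il1rn fell 2.36-fold, the chemokine Ccl6 2.57-fold and the cytokine Il18 1.92-fold.

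Of the metabolic lists, sterol and fatty acid synthesis fell (median -0.49, camera adjusted p = 2.00e-04, adjusted p = 0.403 with estimated correlation, 9.12e-06 to 0.403 over 23 alternatives). In it, of 27 measured genes 2 rose, 16 fell and 9 did not pass (2 rose and 18 fell adjusted over the list alone). The enzymes Msmo1 and Hmgcs1 fell by 0.93 and 0.55, and the regulator Srebf2 by 1.05, although another Srebf2 probe, above background on all 12 arrays, gave 0.34. In autophagy, of 26 measured genes 2 rose, 7 fell and 17 did not pass (2 rose and 8 fell adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0445, adjusted p = 0.403 with estimated correlation, 0.00119 to 0.403 over 23 alternatives). The ubiquitin-like proteins Map1lc3b and Gabarapl2 fell by 0.52 and 1.03, and Atg7 by 0.53. The autophagy call ended without wild-type progenitor array 1, 2 or 3, Rheb1-/- progenitor array 3, wild-type myeloid cell array 1 or 3 or Rheb1-/- myeloid cell array 1 (adjusted p 0.0557 to 0.0867). mTORC1 components did not pass as a list (median -0.12, adjusted p = 0.220), with 6 of 39 rising, 9 falling and 24 not passing (6 and 9 adjusted over the list alone). Rps6, the ribosomal protein phosphorylated downstream of mTORC1, rose by 1.14, and Sesn1 and Akt2 fell by 0.64 and 0.53. ATF4 targets did not pass (median 0.11, adjusted p = 0.161), 6 rising, 4 falling and 15 not passing (6 and 6 over the list alone). The serine synthesis enzyme Phgdh rose by 1.04, the arginine transporter Slc7a1 by 0.67 (another probe above background on all 12 arrays gave -0.14), and Chac1 fell by 0.85. Glycolysis had 3 rising, 3 falling and 18 not passing (3 and 3 over the list alone, median -0.04, adjusted p = 0.934), with Pdk1 at 1.01, Vegfa at 0.80 and the aldolase Aldoc at -1.38. Mitochondrial respiration had 4 rising, 1 falling and 35 not passing (4 and 0 over the list alone, median 0.09, adjusted p = 0.0590), with cytochrome c (Cycs) at 0.58, Uqcrfs1 at 0.41 and Uqcrc1 at 0.40. The list passed without wild-type progenitor array 1 (adjusted p = 0.0496), wild-type myeloid cell array 1 (0.0487) or 2 (0.0341), or Rheb1-/- myeloid cell array 1 (0.0212).

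Markers of other blood lineages were lower in the same Rheb1-/- myeloid cells. Of 21 erythroid markers 20 fell and 1 did not pass (21 fell adjusted over the list alone, median -2.03, camera adjusted p = 2.04e-07, adjusted p = 0.403 with estimated correlation, 2.82e-10 to 0.403 over 23 alternatives), with the blood group gene Rhd down 5.15-fold, Hemgn 3.91-fold and the erythropoietin receptor 3.74-fold. Of 18 B cell markers 12 fell and 6 did not pass (15 over the list alone, median -1.56, camera adjusted p = 1.42e-05, adjusted p = 0.403 with estimated correlation, 1.85e-07 to 0.403 over 23 alternatives), including the B cell receptor chains Cd79a (-1.55) and Cd79b (-1.09) and the co-receptor Cd22 (-1.98). Of 24 T and NK cell markers 13 fell and 11 did not pass (15 over the list alone, median -0.92, camera adjusted p = 4.44e-05, adjusted p = 0.403 with estimated correlation, 1.63e-06 to 0.403 over 23 alternatives). The T cell receptor chain Cd3d fell 7.30-fold and the kinases Lck and Zap70 fell by 1.46 and 0.92. Megakaryocyte and platelet markers (9 of 18 fell, 9 did not pass, 12 over the list alone, median -0.998, camera adjusted p = 3.90e-04, adjusted p = 0.403 with estimated correlation, 1.62e-05 to 0.403 over 23 alternatives) included Pdzk1ip1 (-1.17), Clec1b (-1.08) and Gp1bb (-0.96). Eosinophil, basophil and mast cell markers (7 of 20 fell, 13 did not pass, 7 over the list alone, median -1.18, camera adjusted p = 0.00451, adjusted p = 0.446 with estimated correlation, 9.45e-05 to 0.446 over 23 alternatives) included the eotaxin receptor Ccr3 (-2.21) and the proteases Mcpt8 (-1.57) and Cma1 (-1.13). Dendritic cell markers (6 of 19 fell, 13 did not pass, 6 over the list alone, median -1.07, camera adjusted p = 0.00451, adjusted p = 0.403 with estimated correlation, 5.20e-04 to 0.403 over 23 alternatives) included Itgax (-1.99), Zbtb46 (-1.47) and Ccr9 (-1.14). The median was -0.49 with normexp. Of the 4 other Zbtb46 probes, 1 above background on 5 arrays gave 0.04 and 3 above it on none gave 0.26 to 0.37, and over 25 alternatives Zbtb46 lay between -1.82 and -0.09 (adjusted p up to 0.887). Stroma and endothelium did not pass as a list (median -0.42, adjusted p = 0.147), with 2 of 13 falling, 11 not passing and 2 falling over the list alone, the chemokine Cxcl12 (-1.75) and Kdr (-0.70, a call kept in 14 of 25 alternatives). In myeloid cells 20 of the 29 lists passed camera, 6 higher and 14 lower. With the estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry called 22.

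**Figure D3:**
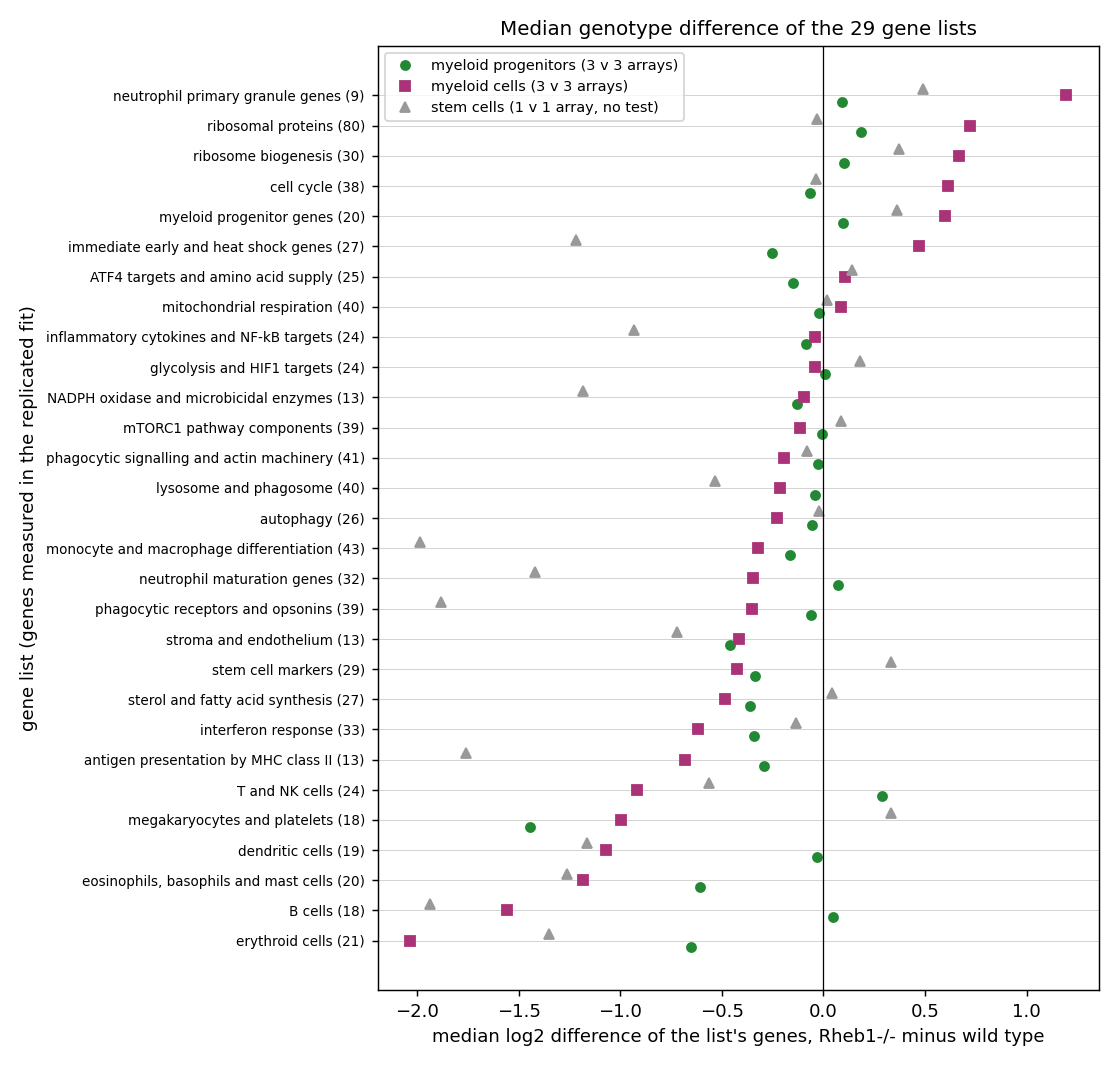
Median log2 difference, Rheb1-/- minus wild type (x axis), of the measured genes of each of the 29 gene lists (y axis), with 1 point per list for progenitors, myeloid cells and the pair of stem cell arrays. Primary granule genes (1.19) and erythroid markers (-2.03) bound the myeloid cell medians, and megakaryocyte and platelet markers (-1.45) had the lowest median in progenitors.

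The genotype difference in myeloid cells minus that in progenitors was tested, so slide and sex of myeloid cell arrays may enter. The difference in myeloid cells lay above that in progenitors for ribosome, cell cycle, primary granule and stress genes, and below it for lymphocyte and dendritic cell markers. These list calls were lost with an estimated correlation (camera adjusted p = 0.221 or higher). Maff differed by 3.66 ± 0.52 (SE, n = 3 per group, limma adjusted p = 0.00919), Fosl1 by 3.37, Atf3 by 2.76 and the myosin light chain Myl10 by 3.41. Fam110c also passed. It was at background in the other 3 groups, so the size is open (0.57 to 3.73 over 23 alternatives). The lowest differences were those of Eif2s3y (-8.58), Klk1b24 (-8.44), Ddx3y (-7.10), Kdm5d (-5.21) and Col6a3 (-5.15), genes not well above background on any Rheb1-/- myeloid cell array, so that their sizes depend on the background there. The Y-linked Eif2s3y, Ddx3y and Kdm5d may reflect sex. Rheb itself did not pass (0.20 ± 0.31 SE, limma adjusted p = 0.700).

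Of 17723 genes 1922 passed, 983 above and 939 below 0 (212 and 462 by at least 2-fold), and 5399 had an unadjusted p under 0.05. The share above 0 was 51.1%, against 63.5% with quantile normalization and 63.7% with the deposited values. The count was 924, 1099 and 1172 without Rheb1-/- progenitor arrays 1, 2 and 3, 1219 and 1184 without wild-type progenitor arrays 1 and 2, 1102 and 1043 without wild-type myeloid cell arrays 2 and 3, and 1084 and 978 without Rheb1-/- myeloid cell arrays 2 and 3. Ribosomal protein genes differed by a median of 0.55 (camera adjusted p = 5.58e-25, adjusted p = 0.332 with estimated correlation, 1.52e-33 to 0.332 over 22 alternatives), 33 of 80 passing upwards and 65 adjusted over the list alone, with Rps7 at 0.85 and Rps3a1 at 0.76. Ribosome biogenesis differed by 0.59 (camera adjusted p = 1.35e-12, adjusted p = 0.221 with estimated correlation, 1.90e-14 to 0.221 over 22 alternatives), 15 of 30 passing upwards and 19 up and 1 down adjusted over the list alone, with Myc at 1.52, Nop58 at 1.02 and Nop56 at 0.76. Cell cycle genes differed by 0.67 (camera adjusted p = 2.67e-16, adjusted p = 0.221 with estimated correlation, 2.33e-21 to 0.221 over 22 alternatives), 19 of 38 passing upwards and 33 adjusted over the list alone. The examples are the helicase subunits Mcm3 (0.73) and Mcm4 (0.73) and the spindle checkpoint kinase Bub1 (0.90), whose other probe, above background on all 12 arrays, gave -0.41 in myeloid cells.

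Primary granule genes differed by 1.09 (camera adjusted p = 1.02e-05, adjusted p = 0.340 with estimated correlation, 5.32e-08 to 0.340 over 22 alternatives), 6 of 9 passing upwards and 8 adjusted over the list alone (Cst7 1.26, Ctsg 1.24, Nkg7 1.20). Myeloid progenitor genes differed by 0.62 (camera adjusted p = 3.98e-05, adjusted p = 0.221 with estimated correlation, 4.33e-07 to 0.221 over 22 alternatives), 7 of 20 and 12 over the list alone (Cdk6 0.98). Immediate early and heat shock genes differed by 0.78 (camera adjusted p = 5.61e-06, adjusted p = 0.426 with estimated correlation, 5.03e-10 to 0.426 over 22 alternatives), 3 of 27 passing, 3 over the list alone (Jun 2.07, Hsp90aa1 0.78). ATF4 targets differed by 0.28 (camera adjusted p = 0.00676, adjusted p = 0.271 with estimated correlation, 0.00502 to 0.271 over 22 alternatives), 4 up and 1 down of 25, 7 and 1 over the list alone, with the regulator Atf4 at 0.99, Phgdh at 0.91 and Chac1 at -1.43. T and NK cell markers differed by -1.07 (camera adjusted p = 1.80e-06, adjusted p = 0.390 with estimated correlation, 2.35e-08 to 0.390 over 22 alternatives; 7 of 24, 13 over the list alone; Zap70 -1.44, Cd3d -1.92, Cd2 -1.91). B cell markers differed by -1.63 (camera adjusted p = 5.63e-06, adjusted p = 0.390 with estimated correlation, 2.58e-08 to 0.390 over 22 alternatives; 5 of 18, 11 over the list alone; Cd79a -1.82, Cd22 -1.96). Erythroid markers differed by -1.34 (camera adjusted p = 4.46e-04, adjusted p = 0.688 with estimated correlation, 2.65e-06 to 0.688 over 22 alternatives).

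Dendritic cell markers differed by -0.95 (camera adjusted p = 0.0174, adjusted p = 0.619 with estimated correlation, 8.84e-04 to 0.619 over 22 alternatives; 2 of 19, 4 over the list alone; Zbtb46 -2.09, -2.41 to -0.02 over 24 alternatives, call kept in 22; Ccr9 -1.47). Neutrophil maturation genes differed by -0.48 (camera adjusted p = 0.0178, adjusted p = 0.849 with estimated correlation, 3.94e-07 to 0.849 over 22 alternatives; 2 of 32, 1 over the list alone; Cd33 -1.49, Padi4 -0.74). Phagocytic signalling and actin genes differed by -0.12 (camera adjusted p = 0.0393, adjusted p = 0.619 with estimated correlation, 4.28e-04 to 0.619 over 22 alternatives; Vav2 -2.29). Mitochondrial respiration differed by 0.11 (camera adjusted p = 0.0378, adjusted p = 0.776 with estimated correlation, 0.00542 to 0.776 over 22 alternatives; Cycs 0.62). These 4 calls ended when single arrays were left out. Leaving out wild-type progenitor array 3, Rheb1-/- progenitor array 1 or Rheb1-/- myeloid cell array 2 ended that of dendritic markers (adjusted p 0.101, 0.0524 and 0.0534), and wild-type progenitor array 1 or 2 or Rheb1-/- progenitor array 1 that of maturation genes (0.0672, 0.179 and 0.0699). Wild-type progenitor array 2, Rheb1-/- progenitor arrays 1 and 3 and Rheb1-/- myeloid cell arrays 1 and 3 did so for actin genes (0.0503 to 0.179), and wild-type progenitor arrays 2 and 3, Rheb1-/- progenitor array 1, wild-type myeloid cell array 3 and Rheb1-/- myeloid cell array 2 for mitochondrial genes (0.0699 to 0.126).

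The remaining lists did not pass the comparison of the genotype differences. Their medians were -0.37 for phagocytic receptors (Cd93 0.89, Lrp1 -0.91 and Adgrb1 -0.51 passing as genes), 0.01 for lysosome genes (Ctsl 1.27, Cd68 -0.71 and Gla 0.73 passing), -0.10 for monocyte and macrophage differentiation (Maf -0.76 and Vcam1 0.94 passing). The median was -0.03 for inflammatory genes (the chemokines Ccl4 at 1.48 and Ccl3 at 1.28, and Tnfaip2 at -0.59, passing), -0.12 for sterol synthesis (Scd2 0.98 among those passing) and 0.03 for stem cell markers (Hoxa9 1.65, Kit 0.67 and Txnip -0.71 passing). For mTORC1 components the median was -0.09 (Rps6 0.96 passing), for glycolysis -0.07 (Pdk1 0.84 passing), for NADPH oxidase -0.16, for autophagy -0.18, for the interferon response -0.26, for MHC class II -0.37, for megakaryocytes and platelets 0.39, for eosinophils, basophils and mast cells -0.55 and for stroma 0.18. Over the alternatives Adgrb1 kept its call in 6 of 24, Fam110c and Gla in 10 of 23, Hoxa9 and Padi4 in 10 of 24, Rps6 and Cycs in 11 of 24, and Myl10 and Hsp90aa1 in 12 of 24. Of the lists, without 1 array, interferon genes passed (wild-type progenitor array 3, adjusted p 0.0287; Rheb1-/- progenitor array 1, 0.0217; wild-type myeloid cell array 3, 0.0274; Rheb1-/- myeloid cell array 1, 0.0268). Megakaryocyte markers did so too (wild-type progenitor array 3, 0.00943; Rheb1-/- progenitor array 1, 0.00359; Rheb1-/- myeloid cell array 2, 0.0167), as did phagocytic receptors (wild-type progenitor array 3, 0.0214; wild-type myeloid cell array 3, 0.0489; Rheb1-/- myeloid cell array 1, 0.0415) and eosinophil markers (Rheb1-/- myeloid cell array 1, 0.0415). Camera called 14 of 29 lists, 8 above and 6 below 0. With the estimated correlation it called 0, with 4 at an unadjusted p under 0.05, and fry called 9.

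The wild-type cell types were compared as a check of the cell type labels. Myeloid cells carried more of the genes of mature neutrophils, phagocytes and lymphocytes, and progenitors more of the genes of ribosome biogenesis, primary granules, early progenitors and mast cells. No list passed with an estimated correlation (camera adjusted p = 0.136 or higher). The gelatinase Mmp9 was 117-fold higher in myeloid cells (log2 6.87 ± 0.19 SE, n = 3 per cell type, limma adjusted p = 6.81e-09), the haem synthesis enzyme Alas2 200-fold, and Gad1, Lyve1 and Krtap21-1 at least 66.9-fold, 30.7-fold and 31.1-fold. Progenitors held 47.0-fold more of the eosinophil granule gene Prg3, 45.3-fold more eosinophil peroxidase (Epx), and at least 29.8-fold and 10.8-fold more Trnp1 and Vit. Slc30a2, above background on 1 of 3 myeloid cell arrays, differed by -5.44. In all, 13765 genes passed, 6866 higher and 6899 lower in myeloid cells, 4444 and 4004 of them by at least 2-fold.

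From progenitors to myeloid cells neutrophil maturation rose (31 rose, 1 fell, 0 did not pass, median 4.39, adjusted p = 3.90e-10, adjusted p = 0.322 with estimated correlation), with the histone-modifying enzyme Padi4 at 4.44 and Cd33 at 5.43. Monocyte and macrophage differentiation rose (38 rose, 2 fell, 3 did not pass, median 2.20, adjusted p = 6.56e-08, adjusted p = 0.209 with estimated correlation), with the immunoglobulin receptor Fcgr1 at 4.41 and Ccr2 at 2.21. Phagocytic receptors rose (33 rose, 4 fell, 2 did not pass, median 2.31, adjusted p = 1.67e-06, adjusted p = 0.136 with estimated correlation), with Tlr2 at 3.14 and Tyrobp at 2.16. Phagocytic signalling and actin genes rose (37 rose, 0 fell, 4 did not pass, median 1.05, adjusted p = 9.59e-09, adjusted p = 0.136 with estimated correlation), with Lyn at 2.38. Interferon genes rose (30 rose, 2 fell, 1 did not pass, median 2.37, adjusted p = 5.07e-08, adjusted p = 0.322 with estimated correlation), with Oas3 at 5.11. Inflammatory genes rose (19 rose, 2 fell, 3 did not pass, median 2.00, adjusted p = 1.89e-04, adjusted p = 0.322 with estimated correlation), with Il1rn at 6.01. MHC class II rose (10 rose, 1 fell, 2 did not pass, median 2.60, adjusted p = 0.00746, adjusted p = 0.322 with estimated correlation), with Cd40, above background on 2 of 3 progenitor arrays, at 3.88. Lysosome genes rose (21 rose, 7 fell, 12 did not pass, median 0.49, adjusted p = 0.00687, adjusted p = 0.322 with estimated correlation), with Cd68 at 2.45. NADPH oxidase rose (10 rose, 3 fell, 0 did not pass, median 2.02, adjusted p = 0.00838, adjusted p = 0.322 with estimated correlation), with Slc11a1 at 5.89. Autophagy rose (18 rose, 4 fell, 4 did not pass, median 0.76, adjusted p = 0.00353, adjusted p = 0.209 with estimated correlation), with Optn at 2.68.

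Ribosome biogenesis fell from progenitors to myeloid cells (0 rose, 29 fell, 1 did not pass, median -2.47, adjusted p = 1.05e-10, adjusted p = 0.136 with estimated correlation), with Nop58 at -3.12. Ribosomal proteins fell (1 rose, 75 fell, 4 did not pass, median -0.92, adjusted p = 1.05e-10, adjusted p = 0.322 with estimated correlation), with Rpl14 at -2.43. Myeloid progenitor genes fell (1 rose, 18 fell, 1 did not pass, median -1.97, adjusted p = 3.47e-05, adjusted p = 0.136 with estimated correlation), with Cd34 at -5.02. Stem cell markers fell (4 rose, 20 fell, 5 did not pass, median -2.01, adjusted p = 0.00746, adjusted p = 0.322 with estimated correlation), with Kit at -2.23. Primary granule genes fell (1 rose, 8 fell, 0 did not pass, median -2.16, adjusted p = 0.00407, adjusted p = 0.322 with estimated correlation), with Cst7 at -2.98. Cell cycle genes fell (1 rose, 26 fell, 11 did not pass, median -0.79, adjusted p = 1.43e-04, adjusted p = 0.322 with estimated correlation), with Mcm4 at -1.72. Mitochondrial respiration fell (2 rose, 33 fell, 5 did not pass, median -0.74, adjusted p = 1.97e-05, adjusted p = 0.322 with estimated correlation), with Cycs at -1.74. ATF4 targets fell (5 rose, 17 fell, 3 did not pass, median -0.90, adjusted p = 0.0273, adjusted p = 0.322 with estimated correlation), with Phgdh at -3.35. Eosinophil, basophil and mast cell markers fell (2 rose, 15 fell, 3 did not pass, median -2.77, adjusted p = 0.00792, adjusted p = 0.440 with estimated correlation), with Cpa3 at -4.33. B cell markers rose (16 rose, 0 fell, 2 did not pass, median 2.85, adjusted p = 1.68e-04, adjusted p = 0.322 with estimated correlation). T and NK cell markers rose (21 rose, 1 fell, 2 did not pass, median 1.55, adjusted p = 3.21e-04, adjusted p = 0.322 with estimated correlation), with Cd3d at 5.47. Erythroid markers rose (13 rose, 2 fell, 6 did not pass, median 2.41, adjusted p = 0.0174, adjusted p = 0.636 with estimated correlation), with Hba-a2 at 6.52. Dendritic cell markers rose (14 rose, 3 fell, 2 did not pass, median 2.52, adjusted p = 0.0180, adjusted p = 0.404 with estimated correlation), with Itgax at 3.90. Not passing were mTORC1 components (median -0.11), glycolysis (0.13), sterol synthesis (-0.35), megakaryocytes and platelets (-1.86), stroma (1.24) and immediate early genes (0.44). Counts adjusted over the list alone equalled those over all genes except 76 falling ribosomal protein genes, 6 rising ATF4 targets, 5 rising stem cell markers and 8 rising stroma markers. Camera called 23 of the 29 lists, 14 higher and 9 lower. With the estimated correlation it called 0, with 6 at an unadjusted p under 0.05, and fry called 27.

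In Rheb1-/- cells the same comparison gave 12139 genes, 5225 higher and 6914 lower in myeloid cells (2908 and 3303 by at least 2-fold), with a median over all genes of -0.10. The within-slide values rest on Rheb1-/- progenitor array 3 against the 3 myeloid cell arrays of slide 4, so 1 arm is a single array. The inflammatory cytokine Il1b was 99.2-fold higher (log2 6.63 ± 0.29 SE, n = 3 per cell type, limma adjusted p = 7.46e-08; within the slide 6.66), the formyl peptide receptor Fpr1 differed by 6.15 (within the slide 6.58), Prok2 by 6.11 (6.31), Mmp9 by 6.07 (6.28) and Gad1 was at least 30.4-fold higher. Epx differed by -5.60 (within the slide -5.48), Prg3 by -5.33 (-5.38) and the mast cell protease Cpa3 by -5.28 (-5.00). The Y-linked Eif2s3y and Ddx3y were at least 78.7-fold and 59.7-fold lower in myeloid cells, which may reflect sex. Camera called 19 of 29 lists, 12 higher and 7 lower. With the estimated correlation it called 0 (smallest adjusted p = 0.118), with 6 at an unadjusted p under 0.05, and fry called 25.

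In Rheb1-/- cells neutrophil maturation genes rose (median 4.28, adjusted p = 2.52e-12, adjusted p = 0.281 with estimated correlation). Phagocytic receptors rose (median 2.06, adjusted p = 6.69e-08, adjusted p = 0.118 with estimated correlation). Phagocytic signalling and actin genes rose (median 0.89, adjusted p = 3.29e-10, adjusted p = 0.118 with estimated correlation). Macrophage differentiation genes rose (median 2.00, adjusted p = 1.60e-10, adjusted p = 0.156 with estimated correlation). Inflammatory genes rose (median 2.04, adjusted p = 6.54e-07, adjusted p = 0.214 with estimated correlation). Interferon genes rose (median 2.23, adjusted p = 3.90e-10, adjusted p = 0.281 with estimated correlation). MHC class II genes rose (median 2.63, adjusted p = 0.00416, adjusted p = 0.392 with estimated correlation). Lysosome genes rose (median 0.39, adjusted p = 3.12e-04, adjusted p = 0.281 with estimated correlation). NADPH oxidase genes rose (median 1.58, adjusted p = 0.00114, adjusted p = 0.306 with estimated correlation). Autophagy genes rose (median 0.58, adjusted p = 0.00265, adjusted p = 0.169 with estimated correlation). B cell markers rose (median 1.06, adjusted p = 0.0137, adjusted p = 0.567 with estimated correlation). Immediate early genes rose (median 1.27, adjusted p = 0.0140, adjusted p = 0.594 with estimated correlation). Ribosome biogenesis fell (median -1.83, adjusted p = 1.60e-10, adjusted p = 0.156 with estimated correlation). Ribosomal proteins fell (median -0.36, adjusted p = 3.77e-04, adjusted p = 0.594 with estimated correlation). Mitochondrial respiration fell (median -0.64, adjusted p = 3.18e-05, adjusted p = 0.333 with estimated correlation). Myeloid progenitor genes fell (median -1.09, adjusted p = 2.94e-04, adjusted p = 0.163 with estimated correlation). Stem cell markers fell (median -1.68, adjusted p = 0.00547, adjusted p = 0.385 with estimated correlation). Primary granule genes fell (median -1.07, adjusted p = 0.0332, adjusted p = 0.567 with estimated correlation). Eosinophil, basophil and mast cell markers fell (median -2.97, adjusted p = 0.00265, adjusted p = 0.487 with estimated correlation). Cell cycle genes had a median of -0.07 and did not pass (adjusted p = 0.795), with 10 rising, 15 falling and 13 not passing. Nor did erythroid (1.01), T and NK cell (0.50), dendritic cell (0.88), megakaryocyte (-1.44) and stroma markers (1.65), sterol synthesis (-0.54), ATF4 targets (-0.69), glycolysis (0.11) and mTORC1 components (-0.23) pass.

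Genes called in the same direction in both cell types were few. C4b, Commd10 and Sva rose and Gpt2, Ifi207 and Ms4a7 fell in both. With normexp Sva passed in neither, and the 3 falls not in progenitors. In myeloid cells Commd10 rose by log2 2.42, C4b by 2.71 and Sva at least 1.93-fold, and Gpt2, Ifi207 and Ms4a7 differed by -0.54, -0.70 and -1.11. The 3 shared increases compare with 1.49 expected of independent lists (odds ratio 2.53, Fisher's exact test p = 0.175, two-sided, adjusted p = 0.175 over the 2 tests) and the 3 shared decreases with 0.709 (odds ratio 13.9, Fisher's exact test p = 0.0193, adjusted p = 0.0386). Igkv4-86 and 4932439E07Rik, which rose in progenitors, fell in myeloid cells (-0.66 and -0.65), the latter named after its values were seen. Shared genes were 48 without Rheb1-/- progenitor array 1 and 16 and 19 without wild-type progenitor arrays 2 and 3. They were 3 without Rheb1-/- progenitor array 2 or 3 or wild-type myeloid cell array 2 or 3. The contrasts share the spread but no array, so calls are not independent. Across genes, not independent replicates, the log2 differences correlated at r = 0.215 (rank correlation 0.195). Per the files the probes lie on chromosomes 17 (C4b), 18 (Commd10), 6 (Sva), 8 (Gpt2), 1 (Ifi207) and 19 (Ms4a7).

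The hematopoietic stem cells had 1 array per genotype, so their differences have no replicate check and no test. The Rheb1-/- array held less of the genes of macrophages, B cells and MHC class II presentation, and slightly more of primary granule, ribosome biogenesis and stem cell genes. Of 16654 genes above background on both arrays, 883 were over 2-fold higher and 1045 over 2-fold lower in the Rheb1-/- sample (11.6%, against 2.05% to 4.11% between 2 progenitor arrays of one group and 2.22% to 3.92% between 2 myeloid cell arrays). With normexp the split was 230 higher and 775 lower. The median difference was 0.13 and the arrays correlated at 0.963 across genes. Lowest were Ccr3 (-6.52), the macrophage genes Cd5l (-5.98), Timd4 (-5.75) and Ms4a7 (-5.82), Ccl8 (-5.82), Fcna (-5.81), Cbr2 (-5.72) and Ubd (-5.70). On the wild-type array Cd5l read 5.46, Fcna 4.60 and Ccr3 2.97. Highest were Stra6l (3.83), Olfr531 (3.65), Pawr (3.44), Thbs3 (3.40), Epha1 (2.99), Arhgef33 (2.81), Rai2 (2.78) and Dlk1 (2.64).

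List medians on the stem cell arrays were placed among 10000 random lists of the same size matched on mean expression. Macrophage differentiation (-1.98), B cells (-1.94), phagocytic receptors (-1.88), MHC class II (-1.76), neutrophil maturation (-1.42), erythroid cells (-1.35), eosinophils, basophils and mast cells (-1.26), immediate early genes (-1.22), NADPH oxidase (-1.19), dendritic cells (-1.16), inflammatory genes (-0.93), T and NK cells (-0.56) and lysosome genes (-0.53) lay below all 10000. Stroma (-0.72), interferon (-0.13) and actin genes (-0.08) lay at percentiles 0.01, 0.0900 and 0.400. Primary granule genes (0.49), ribosome biogenesis (0.37) and myeloid progenitor genes (0.36) lay at percentile 100, and stem cell markers (0.33), megakaryocytes and platelets (0.33) and glycolysis (0.18) at 99.8, 96.9 and 95.9. The rest lay between, with medians of 0.14 for ATF4 targets (percentile 72.9), 0.09 for mTORC1 components (47.0), 0.04 for sterol synthesis (26.3), 0.02 for mitochondrial respiration (47.5), -0.02 for autophagy (7.31), -0.03 for ribosomal proteins (32.5) and -0.04 for the cell cycle (7.43), the last pair turning positive with quantile normalization (0.05 and 0.04). Of genes shared by the replicated cell types, the stem cell arrays differed by 1.60 for Commd10, -0.58 for C4b, -0.41 for Gpt2 and -2.01 for Ifi207. Sva, not above background on both, read -8.04 on the wild-type and -3.86 on the Rheb1-/- array.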

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

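Of the tests below, those of X- and Y-linked genes, immature cells, other lineages, slide and scan for the megakaryocyte list, megakaryocyte-lineage cells and the segment around Rheb were chosen only after the result was seen. The genotype difference differed between the cell types by the test of that difference for 1922 genes and 14 lists, and for no list with an estimated correlation (smallest adjusted p = 0.221). Among named genes the log2 difference of differences was 3.66 for Maff, 3.41 for Myl10, 3.37 for Fosl1, 2.76 for Atf3, 2.75 for Fam110c (at background in 3 groups), 1.98 for Tln2, 1.17 for Commd10, -0.72 for Dgat2, -1.19 for Kif1a, -2.39 for Igkv4-86, -3.69 for Fam71b, -4.12 for Olfr1255, -5.15 for Col6a3, -5.21 for Kdm5d, -7.10 for Ddx3y, -8.44 for Klk1b24 and -8.58 for Eif2s3y. List medians were 1.09 for primary granules, 0.78 for immediate early genes, 0.67 for the cell cycle, 0.62 for myeloid progenitor genes, 0.59 for ribosome biogenesis, 0.55 for ribosomal proteins, 0.28 for ATF4 targets, 0.11 for mitochondrial respiration, -0.12 for actin genes, -0.48 for maturation, -0.95 for dendritic cells, -1.07 for T and NK cells, -1.34 for erythroid cells and -1.63 for B cells. As many genes arose in 9 of 100 drawn splits (highest other 3437) and as many lists in 26 (highest other 22), so chance was not excluded by the splits. All 9 kept the real split of the myeloid cell arrays, as 11 of the 100 did, and those breaking it reached at most 1 gene, which points to a structure of the myeloid cell arrays.

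With 10 splits of 6 arrays no share under 0.05 can be had. In progenitors 1 of 10 gave the real 13 genes (highest other 2) and 2 the real 15 lists (highest other 15), in myeloid cells 1 gave 6069 genes (highest other 1) and 1 gave 20 lists (18). Between the wild-type cell types 1 gave 13765 genes (0) and 1 gave 23 lists (22), and between the Rheb1-/- cell types 1 gave 12139 genes (6).

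The first pattern is the number of genes differing by genotype in myeloid cells. Fewer cells of other lineages as the whole cause are argued against by primary granule genes (median 1.19) lying 1.54 above maturation genes (-0.35). A larger share of immature cells may contribute, since genes 4-fold higher in progenitors than in a left-out wild-type array were higher in Rheb1-/- cells for each choice of that array (lowest median 0.516, with -0.618 for progenitor-low genes). Slide and genotype cannot be told apart. With slide as a random block 7930 genes passed and 4 of 29 list results were weaker (normexp 3). By Xist and Y-linked genes sex nearly follows genotype. X- and Y-linked genes made up 3.46% of called (205) and 3.46% of tested genes. This does not gauge sex effects, as most X-linked genes are dosage compensated. Autosomal sex effects stay open, because 1 wild-type array carries the comparison (ratio with Xist as a covariate 0.976 over 5716 genes, 800 called). So does an effect of Rheb1 loss.

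The second pattern is the lower megakaryocyte and platelet genes in Rheb1-/- progenitors, a list call lost with an estimated correlation (adjusted p = 0.131). Slide and scan as the cause are argued against by the median of -1.19 on the slide with both genotypes (-1.45 over all arrays). Fewer megakaryocyte-lineage cells stay open, since the share of lower members (94.4% of 18) restates the pattern and would also arise from lower expression per cell, which stays open too. Pf4, abundant in platelets, read 5.23, 5.26 and 4.56 on wild-type and 3.49, 2.70 and 2.29 on Rheb1-/- arrays. How the progenitors were sorted is not given in the sources used here. Their sample titles say GMP, commonly short for granulocyte-macrophage progenitors, whose usual gate leaves out megakaryocyte-lineage cells.

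The third pattern is the genes called the same way in both cell types. A passenger segment around Rheb is argued against by 0 of 6 genes within 20 Mb of its probe. Pooled neighbours within 1 Mb showed no excess moving the same way (4.199% of 262, 5.20% of tested genes). Pooling leaves linked segments at single genes open, and the Vav1-cre insertion site was not tested. Genotype or unlabelled mouse differences may remain.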

How the results depend on the processing

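The autosomal and 10-array alternatives were chosen after the result was seen, the other tests here before. In progenitors, where 13 genes passed, normexp called 27 (7 higher, 20 lower, 3 shared), array weights 43 (13 shared), an intensity trend with a robust prior 51 (10 shared), no filter 7 (6 shared), slide as a fixed block 4 (3 shared) and the 10 arrays 4 (3 shared). The 4 progenitor arrays of the shared slide called 0 (1384 at an unadjusted p under 0.05 by limma) and the 6 progenitor arrays alone 0 (2149). For the difference of the genotype effects the 1922 genes became 786 with no filter and 3472 with array weights. At least 2-fold left 674 of these, 1395 in myeloid cells, 8448 between the wild-type cell types and 6211 between the Rheb1-/- ones. Genes called in both cell types (6) became 19 with normexp, 3 with no filter, 14 with the strict filter, 30 with array weights, 34 with the intensity trend and 0 with 6 arrays per cell type. In stem cells normexp gave 1005 genes over 2-fold and no filter 4788. Fewer arrays were used in some of these. For the rest the cause was not tested.

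Camera with an estimated correlation called 0 lists in progenitors (4 at an unadjusted p under 0.05), 0 in myeloid cells (4), 0 for the difference (4) and 0 between the wild-type cell types (6). Fry called 2 in progenitors, 22 in myeloid cells, 9 for the difference and 27 between the cell types. Slide as a fixed block left 9 lists in progenitors, and so did the 10 arrays (9). The dendritic cell list in progenitors reversed on the 4 arrays of the shared slide (median 0.41 against -0.03, adjusted p = 0.0312, range over 26 alternatives 0.0312 to 0.950), and the cause was not tested.

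With 1 array left out, Rheb ranged from -1.03 to -0.66 in myeloid cells and from -1.30 to -0.97 in progenitors, where it passed without Rheb1-/- array 1 (adjusted p = 0.0397, range over 24 alternatives 0.0397 to 0.554). Genes numbered 4495 to 6057 in myeloid cells, 6 to 81 in progenitors, 924 to 2177 for the difference, 13074 to 13760 and 11188 to 12234 between wild-type and Rheb1-/- cell types, and 3 to 48 in both cell types. Lists numbered 18 to 20, 13 to 17, 11 to 16 and 23 to 23 in myeloid cells, progenitors, the difference and the wild-type cell types.

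Samples that share a replicate number were not paired by it. Their deviations correlated at -0.01, 0.11 and 0.03 in progenitors and -0.10, -0.06 and -0.15 in myeloid cells, and not every sample correlated best with its own number. With the number as a block limma called 0 genes in progenitors (2037 at an unadjusted p under 0.05), 103 for the difference and 0 in both cell types. Over the settings fixed in advance, named genes kept direction and side of the threshold 4866 times, were weaker 408 times and stronger 61 times, and lists 2435, 182 and 50 times. Normexp gave dim genes smaller differences, some below the bounds.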

Other observations

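No test was run for the values given here. Sex-linked genes differed among arrays of one group. Xist read 4.41, 4.86 and 5.07 on wild-type and 4.79, 4.63 and 5.10 on Rheb1-/- progenitor arrays, on which the Y-linked Eif2s3y read 1.05, 0.08 and 0.49 and 0.51, 0.99 and 0.61. On wild-type myeloid cell arrays Eif2s3y read 1.77, -1.95 and 2.46. The wild-type stem cell array read 4.92 for Xist and 0.18 for Eif2s3y, and the Rheb1-/- one 5.998 and -8.13. The labels used here give no sex and do not say whether samples were pooled.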
